A study of Mus musculus with 3 samples.

How the data were processed

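Chromatin bound by LSD1 (Kdm1a), a histone demethylase, was isolated with an antibody and sequenced from 3 mouse samples, and the files used here cover chromosome X. Each of the 3 groups holds 1 library: MEF, mouse embryonic fibroblasts at day 0; LowK, fibroblasts carrying the reprogramming vector SeVdp(fKOSMaB) at day 20 without Shield1; and MidK, the same at day 20 with 30 nM Shield1. Groups were taken from the sample titles. No input library was used here, so a share of reads is coverage and not enrichment, and no difference has a replicate check.

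Reads were aligned with BWA to mm10, per the submitters' processing notes. Per the series' design text, variants were called with bcftools mpileup and reads were analysed by allele. Tool versions, filters and duplicate removal are not given in the sources used here, and neither is the strain that carries the variant base. The deposited counts give, per the file headers, the depth, the reads with the B6 base and the reads with the variant base at each listed position. The deposited score named reliability in the file headers rates each variant call and was used in 1 alternative only.

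Single-base sites were kept; other entries made up 6.97% of the MEF list, 6.13% of the LowK list and 5.56% of the MidK list. The lists hold 411944, 186841 and 119257 such sites with 883058, 295240 and 203350 reads by allele. Every listed site has a variant read, so a plain variant share is pushed upward. Sites with B6 reads and only 1 variant read made up 2.07% of the sites with B6 reads in MEF, 13.9% in LowK and 19.2% in MidK, and among sites with at least 2 B6 reads 0.311%, 0.372% and 0.544%, so the listing differed between libraries at sites with 1 read of each allele. In data simulated with a true share of 50% and no site listed with B6 reads and 1 variant read, a stricter rule than the lists follow, the reads at listed sites were 73.5% variant at the depth of MEF, 84.5% at that of LowK and 79.9% at that of MidK. The real lists held 85.8%, 90.2% and 81.1% variant reads, above the simulated share in each library. The measures fixed before the data were examined use sites with at least 5 reads in each of the 3 libraries and a minor allele of at least 10% of the summed reads (allele share), or sites listed in all 3 libraries (read share). Only 84 and 2992 sites met these rules. A second allele measure was therefore chosen after seeing the data. It takes sites with at least 2 reads of each allele and at most 20 reads, 1 site per 300 bp, and gives the percent of sites with at least 5 reads and no tie at which the variant base has the majority. In simulated data with a true share of 50% it returned 49.6% for MEF, 50.3% for LowK and 50.4% for MidK, and with a true share of 35% it returned 28.1%, 30.3% and 25.0%. All simulated sites of a run had 1 common share, without call errors, sites truly lacking the B6 base or reads from other copies. Real sites were more mixed: at 8 reads, MEF had 195 sites with variant reads only and 268 with 4 of each. The simulation thus does not test the measure on such mixtures. The measure also leaves out sites with no B6 read, 82.6% of the MEF, 90.4% of the LowK and 84.7% of the MidK sites. These shares include sites with a single read. At exactly 5 reads, before thinning, 4529 MEF, 432 LowK and 104 MidK sites had variant reads only. Those with 3 variant and 2 B6 reads numbered 4436, 746 and 636. Relative to these, the measure left out most at that depth in MEF and least in MidK.

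Genes came from a RefSeq table of assembly GRCm38.p6, the build called mm10. It places 1256 protein-coding and long noncoding genes on chromosome X, and 1 of the 95 genes of the fixed lists, Cnbp2, was not found in it. The table gives no strand, so the planned window of gene body plus 5 kb upstream became the gene body plus 5 kb on both sides, and windows around transcription start sites were not run. Windows of neighbouring genes can share reads, and reads of multi-copy families (Rhox, Btbd35f, Rtl8, Mageb, Cldn34) can come from another copy, so their values are uncertain.

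With 1 library per group, differences were called by size and no p-value was computed. A window of 1 Mb or a gene differed in allele share when the shares lay at least 10 percentage points apart with exact 95% Clopper-Pearson intervals that did not overlap, with at least 50 reads per window or 30 per gene in both libraries. A gene differed in read share when reads per 10000 differed at least 2-fold with exact Poisson intervals that did not overlap, with at least 30 reads in 1 of both libraries. Intervals cover counting error only. They are too narrow here, because 1 read can cover several listed sites and is then counted at each. Ratios at sites listed in all 3 libraries use library totals, and those over all listed sites are relative to the median gene unless stated. The use of all listed sites for read shares was fixed before the data were examined as a second choice. Scaling them to the median gene, the fixed lists over all listed sites, and counts with 1 site per 300 bp were chosen after seeing the data. In simulated reads for LowK over MEF, 52.8% of 2-fold and 98% of 4-fold changes were called; for MidK over MEF it was 47% and 95%, and for MidK over LowK 50% and 98.0%. These simulated reads were independent, unlike the real ones. The 7 fixed gene lists were described by their median and its percentile among 10000 random lists matched on mean read count. Named genes are, per comparison and measure, the 5 largest rises and 5 largest falls that met the size rule, Xist, and the 3 members of each list with the most reads; names starting with Gm or ending in Rik were left out unless in a list. Other genes named are list members that met the size rule or, where a count was 5 or fewer, genes in it, chosen after their values were seen. Some genes that these rules would name are not reported here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.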

Results

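LSD1 chromatin reads on chromosome X were listed by allele in fibroblasts (MEF, day 0) and in cells carrying a reprogramming vector at day 20 without Shield1 (LowK) or with 30 nM Shield1 (MidK), with 1 library per group. Shield1 is a ligand that stabilises proteins fused to a destabilising domain. The lists held 883058 reads at 411944 sites in MEF, 295240 at 186841 in LowK and 203350 at 119257 in MidK. Depth was low, at 2.14, 1.58 and 1.71 reads per site, and 47.4%, 67.7% and 69.7% of sites had a single read. MEF and LowK shared 37884 sites, MEF and MidK 19741, and LowK and MidK 11270. All values below are from single libraries.

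The first comparison asked whether LSD1 reads were split between the B6 allele and the variant allele in the same way in the 3 libraries. At the 84 shared two-allele sites, the variant share was 47.2% in MEF (95% Clopper-Pearson interval 45.7% to 48.7%), 52.4% in LowK (50.4% to 54.4%) and 50.9% in MidK (49.4% to 52.4%). The libraries differed by less than 2 standard errors of the spread along the chromosome. LowK lay 5.18 points above MEF with a jackknife standard error of 4.24 over blocks of 1 Mb, MidK lay 3.67 above MEF (1.93), and MidK minus LowK was -1.51 (3.17). Of the reads behind these shares, 68.4% in MEF, 41.2% in LowK and 53.2% in MidK lay in the 1 Mb window that holds Cldn34d, a claudin-like gene. Asmt, which encodes the last enzyme of melatonin synthesis (X:170672644 to 170678054), was the gene that differed. Its variant share was 70.5% in MEF (61.9% to 78.1%), against 48.6% in LowK (40.0% to 57.2%) and 49.1% in MidK (42.2% to 56.0%), and neither call was kept with 1 site per 300 bp. Cldn34d had shares of 42.7%, 44.1% and 43.9%, and Mid1, a ubiquitin ligase gene, had 43.1%, 39.9% and 48.7%. These 3 genes were all that could be tested. Of the 1 Mb windows, only X:143000001 to 144000000 differed, with 59.1% in MidK and 46.4% in LowK, and not without the deepest 1% of sites.

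A measure chosen after seeing the data covered more of the chromosome. Among sites with at least 2 reads of each allele, the variant base had the majority at 48.5% of 11553 untied sites in MEF (47.5% to 49.4%), at 45.3% of 1827 in LowK (43.0% to 47.6%) and at 23.3% of 3057 in MidK (21.8% to 24.8%). B6 reads thus outnumbered variant reads at most such sites in MidK. At the 84 shared sites MidK minus MEF was 3.67 points over reads but -1.85 as the mean over sites, so they give no direction. Over every gene analysed the values were 47.5%, 47.2% and 24.3%. MidK lay below MEF in all 17 bins of 10 Mb, with intervals apart in 17, and below LowK in 17, with intervals apart in 10. At genes known to escape X inactivation the variant majority was 58.7% of 109 sites in MEF (48.9% to 68.1%), 32.4% of 34 in LowK (17.4% to 50.5%) and 27.6% of 29 in MidK (12.7% to 47.2%). At X-linked genes subject to inactivation it was 41.5%, 63.6% and 31.2%, from 123, 22 and 32 sites. The fibroblast and matrix genes gave 50.3% of 163 sites in MEF, 55.6% of 18 in LowK and 18.8% of 16 in MidK (4.05% to 45.6%), and the X-inactivation centre 57.1% of 49, 72.7% of 11 and 22.2% of 9 (2.81% to 60.01%). The pluripotency and germline genes gave 43.5% of 62 sites in MEF, 64.3% of 14 in LowK and 29.4% of 17 in MidK, and the neural markers 46.5% of 185, 50% of 28 and 35.1% of 37. The immune markers did not have MidK below MEF, at 33.3% of 30 sites in MEF, 66.7% of 6 in LowK and 33.3% of 6 in MidK. Sites that MEF also listed brought the MidK value to 41.1% and the LowK value to 57.7%, and a reliability of at least 20 gave 39.1% and 58.5%.

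**Figure D1:**
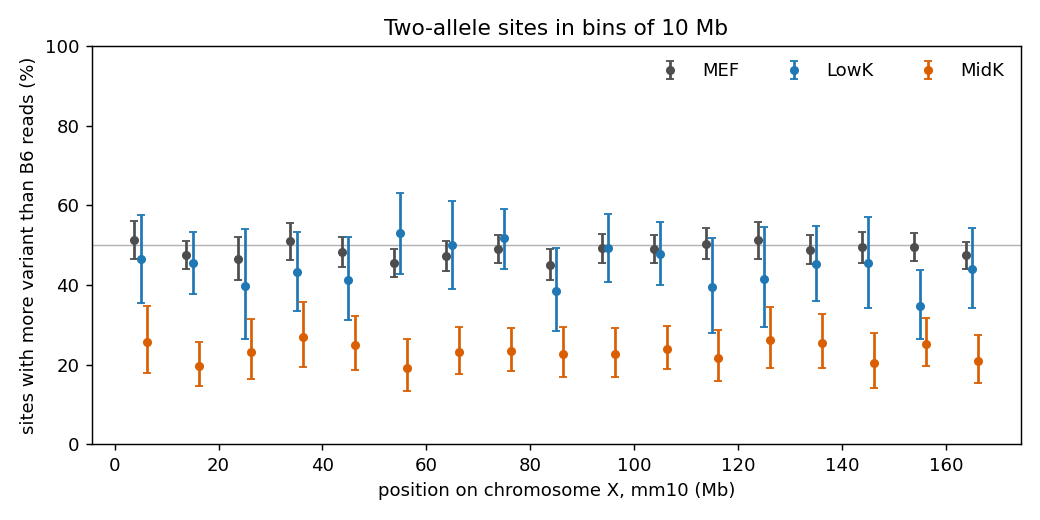
Percent of untied two-allele sites with more variant than B6 reads (vertical axis) by position on chromosome X in Mb (horizontal axis), in bins of 10 Mb, for the MEF, LowK and MidK libraries. Points are 1 library each and bars are 95% Clopper-Pearson intervals; MidK lies between 19.2% and 27.0%, below MEF in all 17 bins.

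**Figure D2:**
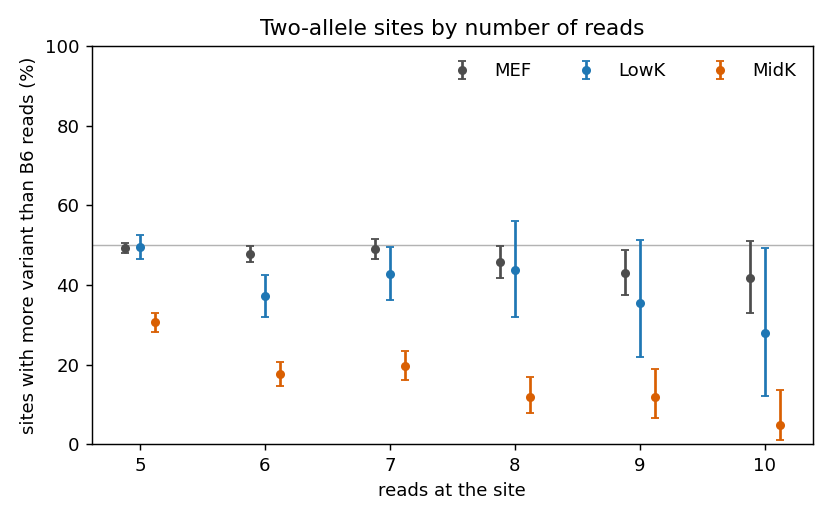
Percent of untied two-allele sites with more variant than B6 reads (vertical axis) by the number of reads at the site (horizontal axis) in each library, with 95% Clopper-Pearson intervals. At 5 reads MEF was at 49.2%, LowK at 49.4% and MidK at 30.6%; at 10 reads they were at 41.8%, 28.0% and 4.92%.

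The second comparison set LSD1 reads per gene in LowK, at day 20, against those in MEF. At sites listed in all 3 libraries, 18 genes could be tested and 4 held a larger share of LowK reads, among them the overlapping Bcor (2.001-fold, 95% interval 1.43 to 2.81) and Gm46687 (2.71-fold, 1.57 to 4.78), and Cldn34c1 (2.32-fold, 1.56 to 3.49). Cldn34d was lower (0.493, 0.461 to 0.527), but over all listed sites its ratio was 1.18 (1.12 to 1.26), and Bcor (1.87) and Gm46687 (1.75) were not called there. Over all listed sites and relative to the median gene, Asmt rose 4.78-fold (4.25 to 5.38; 1.60 at sites listed in all 3 libraries, not called), the semaphorin receptor gene Plxnb3 4.42-fold (3.42 to 5.74), the chemokine receptor gene Cxcr3 3.79-fold (2.58 to 5.61), Magix 3.45-fold (2.67 to 4.47) and Eras, a Ras-like gene of embryonic stem cells, 3.40-fold (2.62 to 4.42). The largest falls were those of Rhox2b, a homeobox gene with 1 read in LowK (ratio 0.0599, 0.00149 to 0.351), Btbd35f21 (0.0931, 0.0250 to 0.245), Mageb1 with 2 reads (0.134, 0.0157 to 0.515), Rhox3f with 3 (0.172, 0.0344 to 0.534) and the receptor gene P2ry10 (0.190, 0.0963 to 0.340). In all, 79 genes were higher and 68 lower of 1080. Scaled to library totals it was 103 and 61, a shift of 0.09 on the log2 scale, and at shared sites scaling to the median gene turned 4 higher and 1 lower into 0 and 3. With 1 site per 300 bp and all its reads, 33 were higher and 14 lower of 942, and with each such site counted once, 0 and 1 of 557. With all reads of these sites, the log2 ratio of Asmt went from 2.26 to 1.01, that of Plxnb3 from 2.14 to 1.68, of Cxcr3 from 1.92 to 1.83, of Magix from 1.79 to 1.55, of Eras from 1.77 to 1.19 and of P2ry10 from -2.40 to -1.50, all still called. Rhox2b (-4.06 to -2.86), Btbd35f21 (-3.43 to -1.22), Mageb1 (-2.90 to -1.39) and Rhox3f (-2.54 to -1.63) fell below the minimum of 30 reads.

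At sites listed in all 3 libraries, only the escape list had 3 testable members. With library totals, its median log2 ratios were 0.47 in LowK over MEF, 0.07 in MidK over MEF and -0.05 in MidK over LowK. The tested protein-coding and list genes had medians of 0.68, 0.28 and -0.22 there. Among random lists the escape list lay at percentiles 13.8, 24.6 and 49.9, so it did not stand above other genes. Only 1 list member, Mid1, had a testable allele share. Lists are therefore given over all listed sites, as chosen after seeing the data.

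Of the pluripotency and germline genes, 6 of 16 rose and 0 fell in LowK over MEF. Sox3, a transcription factor gene, rose 2.49-fold (1.80 to 3.43), Rhox6 2.33-fold (1.64 to 3.30), Tfe3, a transcription factor gene, 2.18-fold (1.71 to 2.78), the phosphatase gene Dusp9 2.17-fold (1.64 to 2.86), Trap1a 2.11-fold (1.46 to 3.05) and Rhox5 2.04-fold (1.27 to 3.24). The list's median log2 ratio was 0.71 (bootstrap interval 0.05 to 1.08), at the 99.9th percentile of random lists. Klf8, Tex11 and Zfx, its members with the most reads, had ratios of 0.931, 1.204 and 1.02. With 1 site per 300 bp, each counted once, the median was 0.04 over the 6 members still testable and 0.36 over all 16. Of the fibroblast and matrix list, 1 of 16 rose, Plp2 (2.33-fold, 1.68 to 3.22), and 1 fell, Itm2a (0.313, 0.157 to 0.569), while Gpc3, Col4a6 and Col4a5 had ratios of 0.615, 0.697 and 0.693; the median was -0.23, at percentile 15.1. The escape list had 1 rise of 11, in 4933407K13Rik (2.44-fold, 2.17 to 2.74), a noncoding gene that was not called with 1 site per 300 bp; Mid1 and Shroom4 had 0.809 and 1.001, and the median was 0.02 (percentile 83.8). Of 20 genes subject to inactivation, Flna, the filamin A gene, rose 2.06-fold (1.65 to 2.57), while Cask, Atrx and Huwe1 had 0.784, 0.722 and 0.596; the median was 0.12 (percentile 72.6). None of 11 testable X-inactivation centre genes met the rule, with Xist, the noncoding RNA that starts X inactivation, at 0.889 (0.673 to 1.16), Tsix at 0.931 and Ftx at 1.02, and a median of 0.09 (percentile 68.3). Immune markers had 1 rise of 10, Cxcr3, with Btk at 1.23, Cybb at 0.670 and Tlr7 at 0.510 and a median of 0.38 (percentile 85.8). Neural markers had 0 calls of 10, with Il1rapl1 at 0.678, Pcdh11x at 0.740 and Gria3 at 0.689, and a median of -0.45 (percentile 1.90), near the low end of random lists; 7 lists were set against random lists in each of 3 comparisons.

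The third comparison set MidK, at day 20 with Shield1, against MEF. At sites listed in all 3 libraries, 3 genes were higher and 2 lower of 17 tested. The sodium-proton exchanger gene Slc9a7 was 2.84-fold higher (1.44 to 5.93) and Mid1 2.57-fold (2.18 to 3.05), while Lancl3 (0.338, 0.157 to 0.672) and 4933407K13Rik (0.421, 0.300 to 0.582) were lower. Relative to the median gene over all listed sites Slc9a7 was at 1.55, Lancl3 at 0.723 and 4933407K13Rik at 1.26 (log2 0.33, against -0.11 with library totals), none called. Over all listed sites and relative to the median gene, Asmt rose 14.0-fold (12.6 to 15.7; 1.75 at sites listed in all 3 libraries, not called), Rhox2h 5.90-fold (4.01 to 8.67), the histone gene H2bfm 4.96-fold (3.49 to 7.02), Cldn34d 4.75-fold (4.53 to 4.99; 0.952 at sites listed in all 3 libraries, 0.905 to 1.001) and Taf9b, a gene of the general transcription machinery, 4.69-fold (3.38 to 6.50). Itm2a (0.0546, 0.00137 to 0.311), the exonuclease gene Trex2 (0.0596, 0.00149 to 0.340), Rtl8b (0.0615, 0.00154 to 0.351) and Rtl8c (0.0868, 0.00217 to 0.49999) each had 1 read in MidK, and Btbd35f25 had 2 (0.0983, 0.0118 to 0.363). In all, 104 genes were higher and 105 lower of 1080. Scaled to library totals it was 48 and 230, a shift of -0.44, and at shared sites 3 higher and 2 lower became 2 and 3 relative to the median gene. With 1 site per 300 bp and all its reads, 47 were higher and 10 lower of 940, and with each such site counted once, 0 and 0 of 556. With all reads of these sites, the log2 ratio of Asmt went from 3.81 to 1.90, of Cldn34d from 2.25 to 1.79, of Taf9b from 2.23 to 1.94, of Itm2a from -4.19 to -3.42, of Trex2 from -4.07 to -3.08 and of Btbd35f25 from -3.35 to -2.59, all still called. Rhox2h (2.56 to 1.36), H2bfm (2.31 to 1.97) and Rtl8b (-4.02 to -2.59) fell below the minimum of 30 reads, and the intervals of Rtl8c (-3.53 to -2.92) overlapped. With each such site counted once, Cldn34d was at 0.74 and not called.

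In MidK over MEF the fibroblast and matrix genes had 0 rises and 3 falls of 16: Srpx (0.453, 0.353 to 0.574), Tmsb4x, a thymosin gene with 2 reads in MidK (0.144, 0.0171 to 0.537), and Itm2a. The list's median log2 ratio was -0.43 (-0.71 to -0.25), at percentile 1.73, and was -0.14 with 1 site per 300 bp, each counted once. Gpc3 had 0.655, Col4a6 0.828 and Col4a5 1.33. Of 16 pluripotency and germline genes, Trap1a (4.51-fold, 3.11 to 6.49), Rhox5 (2.26-fold) and Dusp9 (2.13-fold) rose and Magea4 (0.336, 0.132 to 0.713) and Nono (0.490, 0.298 to 0.765) fell. Library totals lower these log2 ratios by 0.44, which takes Rhox5 (log2 1.18) and Dusp9 (1.09) below 2-fold but not Trap1a (2.17). Klf8 had 1.15, Tex11 1.74 and Zfx 1.15, and the median was 0.21 (percentile 85.7). Of the X-inactivation centre, Jpx, a noncoding activator of Xist, fell (0.320, 0.163 to 0.571), while Xist was at 1.37 (0.997 to 1.86; log2 0.46, against 0.01 with library totals and -0.10 with 1 site per 300 bp and all its reads), Tsix at 1.18 and Ftx at 1.14, with a median of -0.13 (percentile 40.6). The escape list had 1 rise of 11, in Mid1 (2.28-fold, 2.12 to 2.45), which was not called with library totals or with 1 site per 300 bp, with 4933407K13Rik at 1.26, Shroom4 at 1.07 and a median of 0.33 (percentile 89.6). Genes subject to inactivation had 0 calls of 20, with Cask at 0.756, Atrx at 0.745 and Huwe1 at 0.983 and a median of -0.05 (percentile 32.2). Immune markers had 0 calls of 10, with Btk at 0.927, Cybb at 1.27 and Tlr7 at 0.705 and a median of 0.17 (percentile 76.3). Neural markers had 1 fall of 10, with Il1rapl1 at 1.09, Pcdh11x at 1.29 and Gria3 at 0.826 and a median of -0.15 (percentile 16.4).

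The last comparison set MidK against LowK, which differ in Shield1. At sites listed in all 3 libraries 0 genes were higher and 2 lower of 16: 4933407K13Rik (0.274, 0.195 to 0.378) and Gm46687 (0.310, 0.159 to 0.573). Relative to the median gene over all listed sites they were at 0.526 and 0.705 and not called. With library totals over all listed sites, 4933407K13Rik was called lower too (log2 -1.49). Over all listed sites and relative to the median gene, Rhox2h rose 6.41-fold (3.76 to 11.4), P2ry10 5.88-fold (2.96 to 12.5), the ubiquitin protease gene Usp51 4.78-fold (2.63 to 9.03), the homeobox gene Tgif2lx1 4.42-fold (2.31 to 8.81) and Cldn34-ps 4.36-fold (2.63 to 7.44). Rtl8c (0.0310, 0.000773 to 0.178), Trex2 (0.0389, 0.000967 to 0.226) and Rtl8b (0.0648, 0.00159 to 0.387) each had 1 read in MidK, and the deubiquitinase gene Otud6a (0.0838, 0.00988 to 0.319) and Btbd35f25 (0.0872, 0.0103 to 0.332) had 2. In all, 79 genes were higher and 108 lower of 906. Scaled to library totals it was 24 and 264, a shift of -0.56, and at shared sites 0 higher and 2 lower became 2 and 2 relative to the median gene. With 1 site per 300 bp and all its reads, 22 were higher and 21 lower of 566, and with each such site counted once, 0 and 2 of 356. Of the 79 higher and 108 lower genes, 12 and 16 kept the call with all reads of these sites, and 1 higher gene was called lower. With all reads of these sites all of the 10 genes named above fell below the minimum of 30 reads, and Usp51 also below 2-fold, from 2.26 to 0.74 on the log2 scale. Tgif2lx1 went from 2.14 to 2.38, P2ry10 from 2.56 to 2.28, Rhox2h from 2.68 to 1.70 and Cldn34-ps from 2.13 to 1.51. Rtl8c went from -5.01 to -3.66, Trex2 from -4.69 to -3.22, Rtl8b from -3.95 to -2.94, Otud6a from -3.58 to -2.38 and Btbd35f25 from -3.52 to -1.46.

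Of 15 testable pluripotency and germline genes, Trap1a rose 2.18-fold (1.47 to 3.23) in MidK over LowK and Tfe3 (0.379, 0.229 to 0.6001), Sox3 (0.169, 0.06005 to 0.385) and Magea4 (0.267, 0.103 to 0.588) fell. Library totals lower these log2 ratios by 0.56, which takes Trap1a (log2 1.12) below 2-fold. Klf8 had 1.26, Tex11 1.47 and Zfx 1.15, and the median was 0.10 (percentile 79.9). Fibroblast and matrix genes had 2 falls of 15, Plp2 (0.267, 0.117 to 0.536) and Tmsb4x (0.110, 0.0128 to 0.423), with Gpc3 at 1.09, Col4a6 at 1.21 and Col4a5 at 1.96 and a median of -0.26 (percentile 3.72). Genes subject to inactivation had 2 falls of 20, Rbmx, an RNA-binding protein gene (0.398), and G6pdx, the glucose-6-phosphate dehydrogenase gene (0.356), with Cask at 0.983, Atrx at 1.05 and Huwe1 at 1.68 (log2 0.75, and -0.11 with 1 site per 300 bp, each counted once) and a median of 0.02 (percentile 40.7). Mid1 rose 2.87-fold (2.62 to 3.15), the only one of 11 escape genes, and was not called with library totals or with 1 site per 300 bp; 4933407K13Rik was at 0.526 (log2 -0.93; -1.49 and called with library totals, 0.22 with 1 site per 300 bp, each counted once), Shroom4 at 1.09 and the median at 0.10 (percentile 20.4). The X-inactivation centre had 0 calls of 10, with Xist at 1.57 (1.08 to 2.27; log2 0.65, against 0.10 with library totals and -0.03 with 1 site per 300 bp and all its reads), Tsix at 1.30 and Ftx at 1.14 and a median of -0.26 (percentile 19.6). Of the other cell type markers, Foxp3 (0.4999) and Cxcr3 (0.389) fell among the immune markers, and 1 of 10 neural markers fell. Btk had 0.768, Cybb 1.93 and Tlr7 1.41, with an immune median of 0.01 (percentile 56.2), and Il1rapl1 had 1.63, Pcdh11x 1.78 and Gria3 1.22, with a neural median of -0.10 (percentile 11.3).

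**Figure D3:**
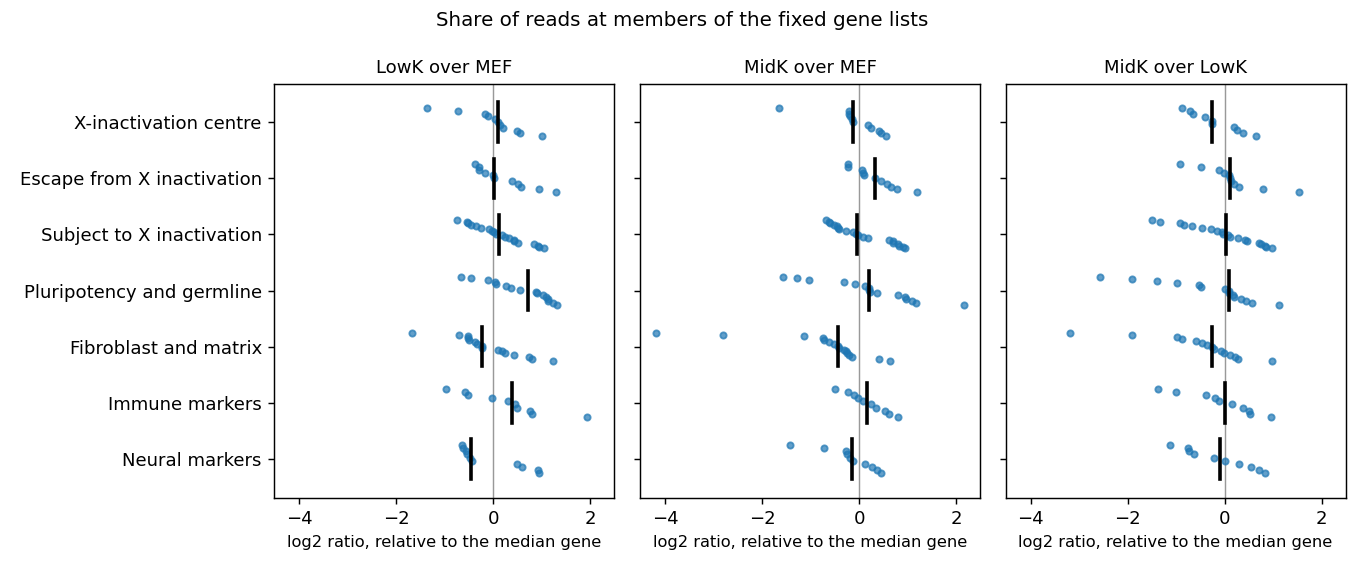
Log2 ratio of the share of reads at all listed sites, relative to the median gene (horizontal axis), for the members of the 7 fixed gene lists (vertical axis) in the 3 comparisons of single libraries. Points are genes and black bars are list medians, such as 0.71 for the pluripotency and germline list in LowK over MEF and -0.43 for the fibroblast and matrix list in MidK over MEF.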

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

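Depth limits the gene and allele results throughout, and counts of calls depend on how sites are counted. The alternatives to the two-allele measure, to the gene counts over all listed sites and to the list medians were chosen after seeing the data. Windows around transcription start sites were not run, because the gene table gives no strand. No paired analysis was possible because each group holds 1 library. The cause of each change below was not tested unless stated.

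For the variant share at shared sites, at least 10 reads gave 45.5% in MEF and 50.3% in LowK. At least 1 read gave 58.0%, 66.5% and 59.2% in MEF, LowK and MidK, with differences of 8.41 (LowK minus MEF), 1.18 (MidK minus MEF) and -7.23 (MidK minus LowK) points, 1 and 2 windows for LowK and MidK against MEF, and 1 gene for MidK against LowK. All informative sites of each library gave 55.8% in MEF and 44.2% in MidK, differences of -2.47, -11.6 and -9.12 points, 11, 106 and 28 windows and 2, 15 and 4 genes; these sites carry the listing bias. A minor allele of at least 25% gave 44.4%, 46.6% and 46.9%, with LowK minus MEF at 2.16. With 1 site per 300 bp it was 53.8%, 59.7% and 58.0%, and 0 genes differed from MEF in LowK and 0 in MidK. The mean over sites gave 60.7%, 58.7% and 58.9%, which turned LowK minus MEF to -2.03 and MidK minus MEF to -1.85. The window that differed between MidK and LowK was not called without the deepest 1% of sites (0) or at 20 points (0).

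For reads per gene at shared sites, the median gene gave 3 genes for LowK over MEF and 4 for MidK over LowK, at least 60 reads gave 3, 3 and 1, and all listed sites gave 164, 278 and 288. Over all listed sites, library totals gave 288 genes for MidK over LowK and at least 60 reads gave 116. With 1 site per 300 bp and all its reads the counts were 47, 57 and 43, against 147, 209 and 187; with every listed site counted once they were 47, 40 and 39; and with 1 site per 300 bp counted once they were 1, 0 and 2, where fewer genes reached 30 counts. Of the 79 genes higher in LowK, 23 kept the call with 1 site per 300 bp and all its reads and 0 with each counted once. That last setting reversed Btbd35f25 (0.076) and Mid1 (-0.24) in MidK over MEF. Among genes not called it turned several, such as 4933407K13Rik (0.22) and Huwe1 (-0.11) in MidK over LowK and Shroom4 (-0.25) in MidK over MEF. Library totals lower the log2 ratios of MidK over MEF by 0.44 and of MidK over LowK by 0.56, which turns the direction of named genes that lay above 0 by less than that, such as Tsix and Ftx. At sites listed in all 3 libraries, with library totals, the ratios of Mid1 and Il1rapl1 in LowK over MEF were 1.38 and 1.85. Over all listed sites both lay below 1 with either scaling. The median gene at the shared sites had a log2 ratio of 0.73, above Mid1 (0.47) and below Il1rapl1 (0.89). Relative to that median only Il1rapl1 kept the other direction, so that of Mid1 depended on the scaling. The ratio of Pcdh11x in MidK over MEF at the shared sites was 0.434. Over all listed sites the log2 ratio of Pcdh11x was 0.37 relative to the median gene and -0.07 with library totals, so its direction there depended on the scaling. The pluripotency and germline median in LowK over MEF was 0.038 with 1 site per 300 bp counted once, over the 6 members still testable, and the fibroblast and matrix median in MidK over MEF was -0.14 with the same thinning. At shared sites, at least 10 reads in each library gave escape medians of 0.54, 0.19 and -0.29 in LowK over MEF, MidK over MEF and MidK over LowK. These use library totals, not the median gene, and lay within the intervals of the values with 30 reads. With all reads of the sites kept at 1 per 300 bp, the escape median in MidK over MEF was 0.042.

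For two-allele sites, a reliability of at least 20 gave 59.0%, 58.5% and 39.1% in MEF, LowK and MidK, sites that LowK also lists 54.7% in MEF, sites that MEF also lists 57.7% in LowK and 41.1% in MidK, and exactly 5 reads 49.4% in LowK and 30.6% in MidK. MidK was the lowest of the 3 libraries under each of these.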

Other observations

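Gene-rich windows of 1 Mb on chromosome X held a larger share of the LowK reads and a smaller share of the MidK reads than of the MEF reads. Over 153 windows of 1 Mb, the log2 ratio of variant reads in LowK over MEF correlated with the number of protein-coding genes at a Spearman rho of 0.54, MidK over MEF at -0.39 and MidK over LowK at -0.63; windows are not independent replicates. Windows with more than 10 genes lay 0.35 above those with at most 2 genes in LowK over MEF, and MidK minus LowK differed by -0.61 on the log2 scale. Protein-coding genes with 5 kb on both sides held 35.3% of the sites in MEF, 34.2% in LowK and 29.8% in MidK. Pooled over the chromosome, genes thus held a slightly smaller share of sites in LowK than in MEF. With library totals, however, the median gene lay 0.09 higher on the log2 scale in LowK over MEF, with 103 genes higher and 61 lower. The pooled share does not show where reads lay inside gene-rich windows, so whether the LowK rise there was at genes stays open.

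Reads were piled up at a few positions. Within Cldn34d, the deepest site had 232 reads in MEF, 126 in LowK and 237 in MidK, and at the 26 MEF sites with at least 50 reads between X:76598582 and 76599124 the variant share ranged from 20% to 98.9%. A pile-up at X:143483048 to 143483091 overlapped no gene of the table and reached 204, 219 and 213 reads. X:170670001 to 170680000, which overlaps Asmt, held 454, 771 and 1080 reads in MEF, LowK and MidK, as many as the whole Asmt window. X:169990001 to 170000000, at the end of Mid1, held 417 reads in MEF and 812 in MidK, where the Mid1 window held 1080. It reaches past that window. Its deepest sites in MidK, X:169994675 to 169994679, lay in the flank past the gene end at 169990798.

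In the 3 patterns weighed here, the tests of gene density, window length and the list's count with 1 site per 300 bp were written before their results were seen, although gene counts with that thinning were already known; the other tests were chosen after the result was seen.

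The first pattern is the B6 majority at two-allele sites of MidK, which the 84 shared sites do not settle: MidK minus MEF was 3.67 points there (standard error 1.93) and -1.85 as the mean over sites. Chance errors among the variant calls would recur little in MEF, yet at sites MEF also lists the MidK variant majority was 41.1% (36.0% to 46.3%) against 57.7% (53.0% to 62.4%) in LowK, which argues against them as the whole cause. Whether they are part of it stays open. MEF listed 7.85% of the MidK sites with a B6 majority and 18.7% of those with 2 variant reads only. A site needs a variant read to be listed, which a site holding only the variant base gives more readily than one with both bases. A lower rate can thus arise without errors, so this comparison cannot decide. Calls that recur in every library, from near-identical copies, stay open: the MidK value was 23.2% without the windows of the deepest pile-ups, but other copies were not located. Reads per site do not account for the pattern, with MidK at 30.6% and LowK at 49.4% at exactly 5 reads. MidK lay below MEF in 17 of 17 bins, and more B6 chromosomes in the cells cannot be told apart from more LSD1 capture on the B6 chromosome without an input library.

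The second pattern is the trend with gene density. Repeated counting of a read does not explain it, since rho for MidK over LowK was -0.65 with 1 site per 300 bp. Base composition of the fragments cannot be told apart from LSD1 binding, because no genome sequence was used; rho with variant reads was -0.63.

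The third pattern is the higher LowK share at pluripotency and germline genes, 1 of 7 lists in 3 comparisons; the neural markers lay at percentile 1.90 in the same comparison. The list stayed at percentile 99.8 of random lists matched on local gene density, and at 99.95 when matched on window length, so neither alone accounts for it. Lists matched on density and length together were not drawn, and both tests used counts in which a read can be counted repeatedly. Repeated counting of reads may account for it: with 1 site per 300 bp, each counted once, the list fell to percentile 54.5. Only 6 of 16 members were then testable, and those 6 had a median of 0.15 before thinning as well. Over all 16 members without a minimum, a test added because of that result, the median was 0.36 at percentile 97.7, too near the bound set to decide, so the pattern remains a hypothesis with this explanation open.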
